A study of Mus musculus with 4 samples.

How the data were processed

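Spleen RNA pools of male and female offspring of CB-NP and control dams were measured on 4 arrays, 1 per group. Per the file headers, the authors scanned 1-colour (Cy3) Agilent arrays of design 028005, drawn on the mouse build mm9, and read them with Agilent Feature Extraction 10.10.1.1. Per the labels, RNA integrity was checked on a Bioanalyzer before labelling. The main deposited column is the processed signal, an intensity on a linear scale. Per the file headers it was background-subtracted and detrended within each array, and it was not normalized between arrays. Other columns per the file headers are the raw median intensity of each spot and of its local background, the propagated error of the processed signal, and other values that are flags of 0 or 1 for spots well above background, saturated or non-uniform. The authors also deposited a value table, an intensity on a linear scale, which equalled the processed signal times 1 constant per array (3.10, 3.18, 2.64 and 3.49 for male control, male CB-NP, female control and female CB-NP). The medians of its columns were 75.2, 76.1, 68.9 and 79.4, and the target of that scaling was not stated.

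Each array held 62976 spots, of which 3671 were controls and 59305 were not. No spot was saturated. Well above background were 34671, 34996, 34619 and 33973 spots in the order given, and the flags marked 154, 154, 180 and 174 spots as outliers. Spots printed repeatedly varied by 4.52%, 4.51%, 4.32% and 4.78% (coefficient of variation), and the spike-in controls followed their known amounts with r-squared values of 0.995, 0.994, 0.995 and 0.993, per the file headers. The median scanner error of a log2 difference between arrays was 0.204. The number of arrays, 1 per group, limits the precision.

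The log2 processed signal was centred on the 75th percentile of the non-control spots of each array. Repeated spots of a probe were averaged, without spots flagged as outliers on that array. Of 55681 probes, 26762 were matched by RefSeq accession to 20284 genes through a table of RefSeq names (assembly GRCm38.p6, used for names and chromosomes only), and 28919 were not matched and were set apart. A gene was represented by its probe with the highest mean over the 4 arrays, since 5405 genes had more than 1 probe. A gene entered a comparison when it was well above background on both arrays, and 15116 genes were so on at least 1 array. Genes well above background on only 1 array of a pair were given a lower bound, computed against the other array's lowest level called well above background, or the gene's own level there if higher. The design assumed a mean-pixel signal and a gene name column, whereas the files give a median-pixel signal and a systematic name, and these were used instead. The software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.

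The comparisons, gene lists, thresholds, named-gene rule and alternatives were fixed before the data were examined, except where stated. Within a sex, genes were counted at a log2 difference of at least 1 (2-fold), with no test. Overlap between the sexes was set beside the number that independent lists would give. A limma model with treatment and sex was fitted over genes well above background on at least 2 arrays, with Benjamini-Hochberg adjustment at 0.05. In simulated data it recovered 1% of 100 genes changed by 1 and 83% of 100 genes changed by 2 on the log2 scale, with 6 false calls among 90. The simulated noise was independent between genes and drawn from the model's own variance prior. These rates therefore do not cover shifts shared by many genes in the real pools.

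The 35 gene lists, of cell types, pathways and neighbouring tissues, held members measured in each pair, and 3 were needed. The median of each list was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins. Percentiles under 2.5 or over 97.5 were called outside the central range, which describes the pools and does not test the exposure. On simulated lists of 20 genes, 100 of 100 lists shifted by 0.5 and 4 of 100 unshifted lists fell outside. Between the control pools, which differ in sex and not in exposure, 12 of 35 real lists fell outside. The simulated rate therefore does not carry over to the real lists. For 15 listed genes no probe was found.

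The genes named were, per sex, the 10 highest and 10 lowest that were at least 2-fold in the same direction also with normexp background correction and that had a gene symbol, the 5 largest bounds in each direction, the 10 highest and 10 lowest in both sexes, up to 5 genes at least 2-fold in opposite directions in each sense, and from each list the members at least 2-fold different in either sex (up to 4) or otherwise the 2 with the highest signal. Not every list member that met this rule is named in the text. The sex markers and Traf6, Ccr7, Ccl19, Cd3e, Cd4 and Cd8a were always given. The genes called lower by limma, and the list members given as further examples (Ms4a1, Pax5, Vpreb1, Vpreb3, Igll1, Dntt, Rag1, Rag2, Cxcr5, Ltb, H2-Eb1, Cd74, Isg15, Itgax, Flt3, Zbtb46, Clec9a, Siglech, Ccr9, Cpa3, Ltf and Ccl3), were added after their values were seen.

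The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, centring on the median, cyclic loess, the authors' value table, detection on all 4 arrays, no detection filter, the mean over a gene's detected probes and a threshold of 1.5-fold. For limma they also included no sex term and an intensity trend in the variance prior. A count without the genes of the pancreatic lists was added after the data were seen. The array positions and the number of animals in a pool were not analysed here.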

Results

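Gene expression was measured in whole spleens of 5-day-old ICR mice, an outbred stock, after maternal exposure to carbon black nanoparticles (CB-NP), which are ultrafine particles of nearly pure carbon. Dams had received CB-NP through the nose 2 times, on gestational days 5 and 9, at 95 microg/kg each time, and control dams had received distilled water at 1 mL/kg. Spleen RNA was pooled within each sex and treatment. The 4 pools (male control, male CB-NP, female control and female CB-NP) were each read on 1 single-colour array. No pool was repeated, so no difference within a sex could be compared with a replicate spread. The scanner error given below covers the reading of the spots only, and the percentiles of gene lists describe these 4 pools. All 4 arrays lay on 1 slide, and array position could not be separated from group. Of the 59305 non-control spots, 58.46% were well above background in the male control, 59.01% in the male CB-NP, 58.37% in the female control and 57.29% in the female CB-NP array. A total of 13933 genes were well above background on all 4 arrays, and the number of arrays limits the precision.

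The control pools of the sexes showed how far pools differed without exposure and whether the labels held. Xist, the RNA that silences an X chromosome in females, was at least 85.3-fold higher in the female control than in the male control. The Y-linked genes Ddx3y and Eif2s3y were at least 107-fold and at least 116-fold lower, and Uty was at least 7.01-fold lower. Kdm5d, also Y-linked, was not well above background on any array. The eosinophil granule genes Prg2 and Epx were higher in the female control by 1.08 and 1.23 on the log2 scale. Genes of neutrophils and of inflammatory cytokines were also higher there, with list medians of 0.27 and 0.41. Megakaryocyte and platelet genes (list median -0.17) and splenic stroma genes (-0.13) were lower. The insulin genes Ins1 and Ins2 were lower in the female control by -3.37 and -2.37. Pancreatic acinar enzyme genes went both ways, with 9 higher and 10 lower (list median -0.05). Of 14163 genes, 36 were at least 2-fold higher and 74 at least 2-fold lower in the female control. This split moved to 9 and 4 with normexp background correction and quantile normalization, to 57 and 46 with median centring, and to 51 and 54 with quantile normalization alone. It moved to 48 and 54 with cyclic loess. Of 35 gene lists, 12 fell outside the central range of random lists between these pools, which differ in sex and not in exposure. Besides those named, they included natural killer cells (0.33) and interferon-stimulated genes (0.18).

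In males, the comparison of CB-NP with control asked which spleen transcripts of male offspring differed after maternal exposure. Digestive enzymes of the exocrine pancreas were the most strongly lower genes in the male CB-NP pool. The elastase gene Cela3a (chromosome 4) was 80.1-fold lower (log2 difference -6.32, scanner error 0.26), the chymotrypsinogen gene Ctrb1 71.2-fold, the colipase gene Clps 33.5-fold and the carboxypeptidase gene Cpa1 26.6-fold lower. The male CB-NP signal of Cela3a was near background at 18.5 intensity units, and another of its probes gave a log2 difference of -2.70. With normexp background correction Cela3a was -4.29, Ctrb1 -4.83, Clps -4.11 and Cpa1 -2.82. Prim2 (chromosome 1), a subunit of DNA primase, was 32.3-fold lower, and Sycn, a zymogen granule protein, and Cela3b were 14.6-fold and 11.3-fold lower. Ins2, 1 of the insulin genes, was 10.9-fold lower. The eosinophil granule genes Prg2 (major basic protein, chromosome 2) and Ear6 (a ribonuclease) differed by -3.33 and -3.16 on the log2 scale. Slc15a2 (chromosome 16), a peptide transporter, was highest among genes with a symbol, well above background on both male arrays and 2-fold higher also with normexp. It was 8.70-fold higher (log2 difference 3.12, scanner error 0.27). Its male control signal was near background at 19.6 intensity units, and its log2 difference was 1.55 with normexp background correction. Its female control signal was 168 units, beside 173 in the male CB-NP pool, and its female log2 difference was -0.37. Cfap126, a gene of motile cilia, was 4.30-fold higher.

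Among genes with a gene symbol that were also at least 2-fold higher with normexp, the 10 highest in the male CB-NP pool included the non-classical MHC class I genes H2-T24 (log2 difference 1.75) and H2-T23 (1.13), the MHC class II gene H2-Ob (1.16) and the interferon-inducible GTPase gene Tgtp2 (1.37). Another probe of H2-T24 gave 0.96, and another probe of Tgtp2 gave 0.24. Tgtp2 was higher by 1.84 in the female control than in the male control, and its female difference was 0.065. Chac1 (1.27), which degrades glutathione, Galk2 (1.22), Fads3 (1.13) and the lipid-sensing receptor gene Gpr132 (1.07) completed these 10. Another probe of Galk2 gave 0.47. Among genes well above background in only 1 of the 2 male pools, Nr1h5 was at least 33.2-fold, Prss22 at least 23.0-fold, Dcpp3 at least 10.5-fold, Best3 at least 6.37-fold and Pip5k1b at least 5.82-fold higher with CB-NP. The largest lower bounds in the other direction were those of the amylase gene Amy2a5 (at least 124-fold lower), the trypsin gene Try5 (at least 73.4-fold), the lipase-related gene Pnliprp1 (at least 57.0-fold), the insulin gene Ins1 (at least 50.4-fold) and Try4 (at least 37.4-fold). Of 14186 genes compared, 49 were at least 2-fold higher and 72 at least 2-fold lower, which was 0.853% of the genes. The authors' scaling moved this split to 68 and 61. With normexp the counts were 13 higher and 22 lower.

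In females the same question was asked of the female pools. The pancreatic enzyme genes were again the most strongly lower. Cela3a was 51.9-fold lower (log2 difference -5.70, scanner error 0.32), Ctrb1 25.2-fold, Cela3b 21.6-fold, Cpa1 15.2-fold, Clps 12.5-fold, the bile salt-stimulated lipase gene Cel 8.80-fold and Sycn 5.51-fold lower. Another probe of Cela3a gave -6.07, and normexp moved Cela3b from -4.43 to -2.31 and Cpa1 from -3.93 to -2.39. The eosinophil genes Ear6, Epx (eosinophil peroxidase) and Prg2 were 6.10-fold, 5.87-fold and 5.14-fold lower. Cfap126 was highest among genes with a symbol, well above background on both female arrays and at least 2-fold higher also with normexp. It was 4.97-fold higher (log2 difference 2.31, scanner error 0.20). Among these genes it was followed by Sfi1 (log2 difference 1.92), the transcription factor gene Tbx22 (1.71), the sialyltransferase gene St6galnac1 (1.54) and the signalling adaptor gene Shc4 (1.53). Lzts3 (1.51), the RNA helicase gene Ddx25 (1.49), Rabgap1 (1.45), the nuclear receptor gene Nr1h5 (1.42) and Pcp4l1 (1.32) completed these 10. Another probe gave 0.74 for Sfi1, -0.78 for St6galnac1, 0.04 for Shc4 and 0.19 for Rabgap1. In the male pair Sfi1 (0.08), Tbx22 (-0.09), Shc4 (0.07) and Ddx25 (0.02) lay near 0, and the differences between the sexes were not tested.

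Among genes well above background in only 1 of the 2 female pools, Zfp641 was at least 7.64-fold, Tmco5 at least 4.89-fold, Lmntd1 at least 4.69-fold, Olfr918 at least 4.04-fold and Slc17a3 at least 3.69-fold higher with CB-NP. In the other direction Amy2a5 was at least 103-fold, Try5 at least 52.8-fold, the cell polarity gene Pard6b at least 49.1-fold, Pnliprp1 at least 48.0-fold and Try4 at least 34.6-fold lower. Of 14075 genes compared, 93 were at least 2-fold higher and 61 at least 2-fold lower, which was 1.09% of the genes. The split moved to 23 and 27 with normexp, to 77 and 79 with quantile normalization, to 65 and 88 with median centring and to 140 and 50 with the authors' scaling. Median centring shifted the median of all genes in the female comparison by -0.111 on the log2 scale, and female values are relative to that choice.

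The male and female comparisons share no array, and their overlap was the only check between pools. The genes lower in both sexes were led by pancreatic enzymes and eosinophil granule proteins, and those higher in both sexes were Cfap126 (log2 differences 2.10 in males and 2.31 in females), H2-Ob (1.16 and 1.29), Efcab9 (1.93 and 1.01) and Fads3 (1.13 and 1.08). Efcab9 was 0.50 and 0.39 with normexp. Of 13933 genes, 24 were at least 2-fold lower in both sexes, against 0.271 for independent lists, and 4 were at least 2-fold higher, against 0.303. The lower genes included 6 members of the pancreatic lists. They also included Cela3a and Sycn, which are not on those lists. A further pancreatic trypsinogen gene, Gm10334 (-4.04 and -2.79), also not listed, was named after its values were seen. The eosinophil granule genes Prg2, Epx, Ear6, Prg3, Ear1 and Ear2 were all among the 24, with Prg3 at -1.87 and -2.09, Ear1 at -1.23 and -1.41 and Ear2 at -1.06 and -1.31. The last 3 were named after their values were seen. Prim2 was -5.01 in males and -1.84 in females. Just under the threshold in 1 or both sexes lay Fcer2a, the low-affinity IgE receptor of B cells (0.95 and 0.92), Il4i1 (0.97 and 0.99), Ell3 (1.11 and 0.97), Ifi214 (0.98 and 1.39), Pla2g2d (0.96 and 1.23) and Trim12c (0.95 and 1.25). No gene was at least 2-fold higher in males and lower in females, against 0.203 for independent lists. The reverse held for 3 genes, against 0.404.

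Across the 13933 genes, the male and female log2 differences had a Pearson correlation of 0.433 and a Spearman correlation of 0.401. Genes are not independent replicates, and no p was computed. Without the genes of the pancreatic lists, left out after the data were seen, the values were 0.399 and 0.400. The pancreatic genes Cela3a, Sycn and Gm10334 are not on these lists and stayed in. The female minus male differences in controls and in CB-NP pools correlated at 0.040 and 0.019. The third pairing, which sets opposite corners of the design against each other and so also contains the treatment contrast, gave 0.398 and 0.377. The spread of the treatment difference averaged over the sexes (SD 0.269) exceeded that of the sex difference averaged over the treatments (0.177) and that of the half-difference between the sexes (0.170). The scatter plot of the male and female differences shows these genes.

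**Figure D1:**
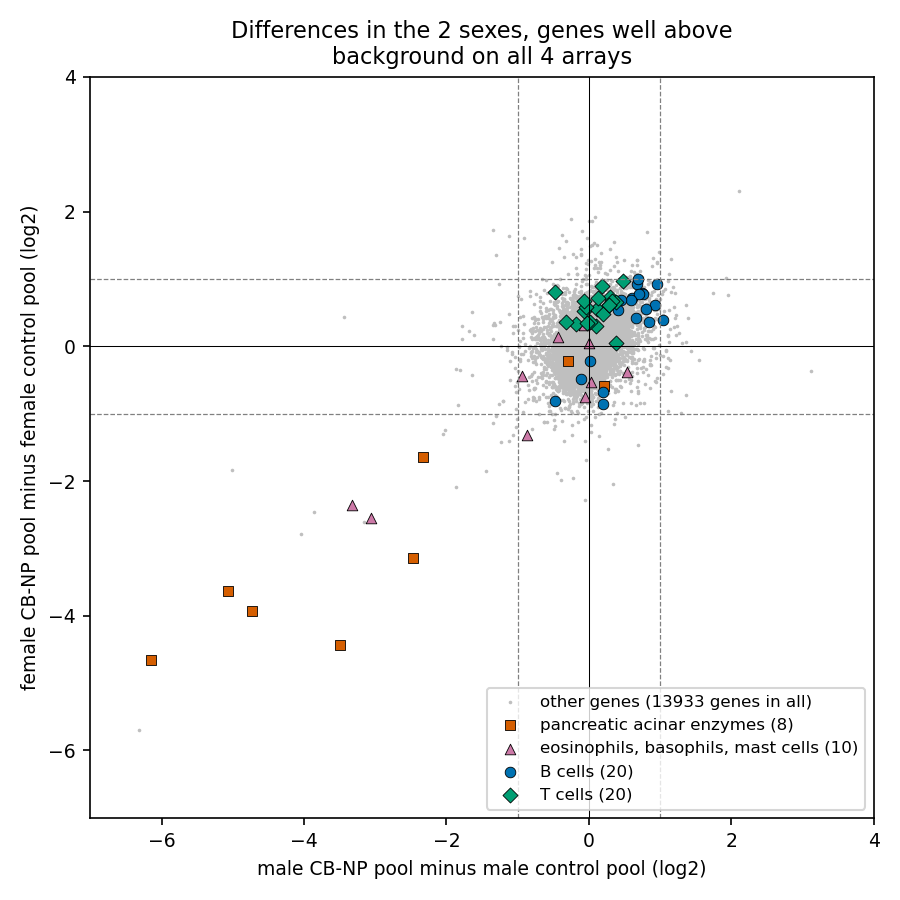
Log2 difference of CB-NP minus control in males (horizontal axis) against females (vertical axis), with 1 point for each of the 13933 genes well above background on all 4 arrays and 1 pool per group. Pancreatic enzyme genes such as Cela3a (-6.32 and -5.70) and eosinophil granule genes such as Prg2 (-3.33 and -2.36) lie far into the lower left, Cfap126 (2.10 and 2.31) lies in the upper right, and the Pearson correlation is 0.433.

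A model over both sexes tested the shared effect of CB-NP, with sex as a term and 1 residual degree of freedom. Cela3a was lower with CB-NP in 2 of 2 pairs (log2 difference -6.01, adjusted p 0.0438 by limma with Benjamini-Hochberg adjustment). The other genes called lower were Amy2a5, Try5, Pnliprp1, Try4, Prss1 and the trypsin inhibitor gene Spink1. They were not well above background in either CB-NP pool, so their fitted values and p rest on readings near the floor and are not given. Prss1 was at least 8.79-fold lower in males and 11.2-fold in females, and Spink1 at least 16.5-fold and 5.32-fold. Of 14501 genes tested, limma called 7 lower and 1 higher, and 1994 had an unadjusted p under 0.05. Among genes well above background on all 4 arrays no gene passed, with 2114 at an unadjusted p under 0.05. Quantile normalization, cyclic loess and the authors' scaling left no gene higher and 3, 3 and 2 lower in limma (1974, 1966 and 2145 unadjusted), and without a detection filter limma called no gene either way (1366 unadjusted). With median centring 169 genes were called higher and 171 lower, and with an intensity trend 226 and 152.

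The gene lists gave the tissue and cell type picture. Pancreatic acinar enzyme genes were 21.8-fold lower in the male CB-NP pool and 21.6-fold lower in the female CB-NP pool by the list median. At least 2-fold lower were 16 of 18 measured members in males and 17 of 19 in females, and the list lay at percentile 0 of random lists in both sexes. Members below the detection limit, 10 in males and 11 in females, were also entered at their bounds, which gave medians of -3.77 and -3.64 on the log2 scale. Islet hormone genes, from the endocrine pancreas, were lower in the male CB-NP pool in 5 of 5 members (list median -3.44, percentile 0). Of these, 3 were not well above background there, and the median with them at their bounds was -2.37. In the female pair, the 3 measured islet genes had a median of 0.49 (percentile 96.97), as with Ins2 (0.44) and Ins1 (0.75). The plot of levels in the 4 pools shows acinar enzymes, eosinophil granule genes and B cell genes side by side.

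**Figure D2:**
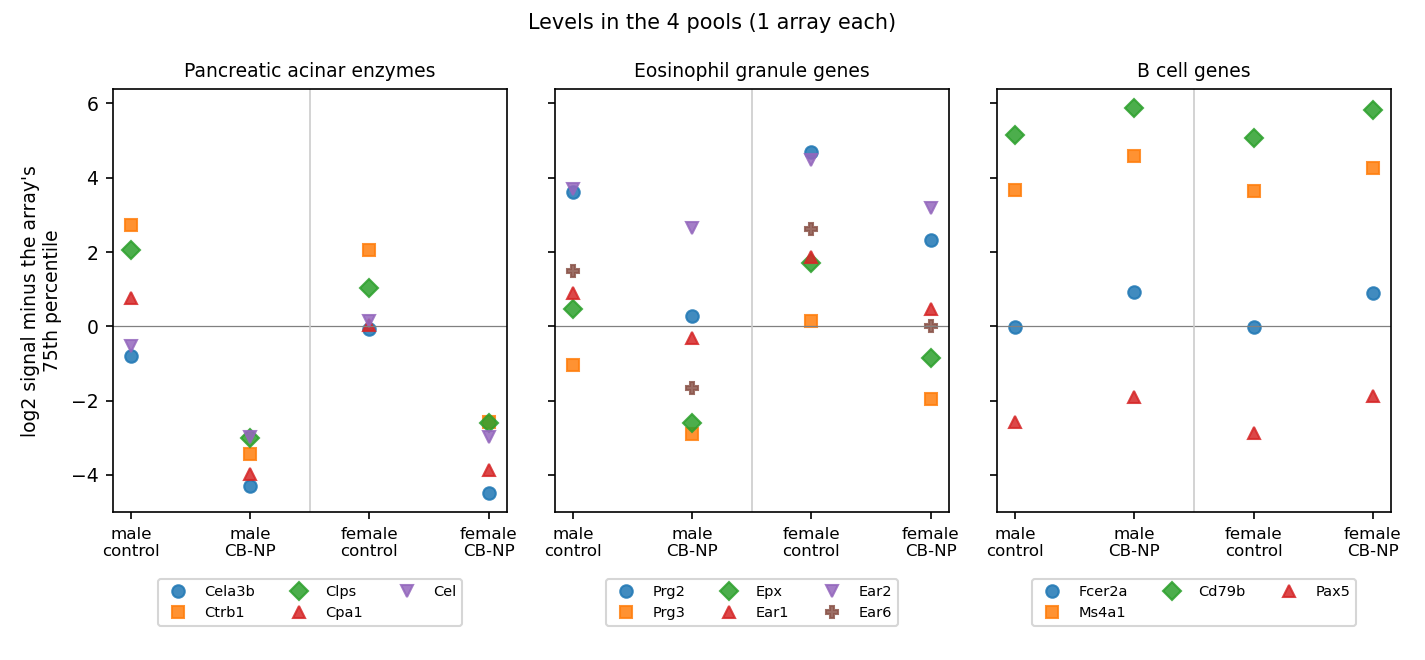
Log2 signal minus the 75th percentile of each array (vertical axis) in the 4 pools (horizontal axis), with 1 symbol per gene and 1 array per pool. Acinar enzymes and eosinophil granule genes lie lower in both CB-NP pools (Ctrb1 by -6.15 and -4.65, Epx by -3.06 and -2.55), and B cell genes such as Ms4a1 lie higher (by 0.92 and 0.61).

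Genes of B cells were higher in both CB-NP pools, by a median of 1.58-fold in males and 1.46-fold in females, while the acinar list medians with members at their bounds were -3.77 and -3.64. Above 0 were 18 of 21 members in males and 15 of 21 in females, at percentile 100 in both sexes, whereas the control pools of the sexes differed by -0.04 (percentile 11.18). The surface protein gene Ms4a1 was 0.92 and 0.61 on the log2 scale, and the transcription factor genes were higher too, with Ebf1 at 1.04 and 0.39 and Pax5 at 0.68 and 1.00. Members of the list that mark B cell precursors lay lower or went both ways, as with Vpreb1 (-0.11 and -0.48), Igll1 (-0.48 and -0.82) and Dntt (0.20 and -0.68). Lymphoid chemokine and homing receptor genes were higher by medians of 0.47 in males (13 of 15 above 0) and 0.49 in females (10 of 14), at percentile 100 in both. Examples were Cxcr5 (0.96 and 0.91), lymphotoxin beta, Ltb (0.77 and 0.74), Ccr7 (0.47 and 0.66) and Ccl19 (0.52 and 0.47).

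Genes of T cells were higher in the female CB-NP pool in 22 of 22 members, with a median of 0.60 at percentile 100 beside an acinar median at bounds of -3.64. In males the T cell median was 0.13 at percentile 98.41, with 14 of 21 members above 0, and normexp moved it to percentile 93.51. The difference between the sexes was 0.44, at percentile 100 of random lists. Cd3e was -0.05 in males and 0.59 in females, Cd8a 0.13 and 0.72, and Cd4 -0.17 and 0.33. Genes of dendritic cells and MHC class II presentation had medians of 0.30 and 0.38 (percentile 100 in both sexes, 10 of 14 members above 0 in each), beside acinar medians at bounds of -3.77 and -3.64. The MHC class II genes, which B cells also express, carried most of this: H2-Eb1 was 0.60 and 1.00 and Cd74, the invariant chain, 0.58 and 0.66, whereas H2-Aa was -1.15 and -0.06. The dendritic cell markers of the list were mixed in females. Itgax (0.32 and -0.16), Flt3 (0.36 and -0.16) and Zbtb46 (-0.80 and -0.51) were lower there. Clec9a (0.08 and 0.50) and Siglech (0.04 and 0.20) were higher, and Ccr9 was at 0.28 and 0.00. Interferon-stimulated genes had medians of 0.14 in males (percentile 99.37, 12 of 18 above 0) and 0.42 in females (percentile 100, 17 of 19 above 0). Isg15 was 0.38 and 0.83, and the list's difference between the sexes was 0.28 (percentile 100).

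Genes of eosinophils, basophils and mast cells were lower in both CB-NP pools, where acinar genes were also lower (-3.77 and -3.64 at bounds), with medians of -0.25 in males (percentile 0.02, 8 of 10 below 0) and -0.52 in females (percentile 0, 8 of 11 below 0). The mast cell carboxypeptidase gene Cpa3 was -0.94 and -0.44 and the mast cell chymase gene Cma1 -0.87 and -1.31, beside Prg2 and Epx. Cell cycle genes were lower by small amounts, with medians of -0.19 (18 of 20 below 0, percentile 0.01) and -0.25 (20 of 20, percentile 0.05). The matched random lists themselves had medians of -0.07 in males and -0.10 in females, so 0 is not the baseline for these counts. Neutrophil granule genes went opposite ways, with a median of 0.09 in males (percentile 100) and -0.38 in females (percentile 0, 18 of 19 below 0). Lactoferrin, Ltf, was 0.02 and -0.84. Megakaryocyte and platelet genes were higher in males (0.30, percentile 100, 13 of 13 above 0) and near 0 in females (-0.01, percentile 83.58), where the sign depended on the scaling. Pf4, platelet factor 4, was 0.29 and 0.01. Inflammatory cytokine and chemokine genes had medians of 0.47 (percentile 100) and 0.08 (percentile 73.21), as with Ccl3 (0.96 and -0.47). Genes of Toll-like receptor and NF-kB signalling had medians of 0.18 (percentile 99.94) and -0.01 (percentile 72.91), and their adaptor gene Traf6 was -0.13 and -0.27. The median per-gene difference of the female from the male values was -0.54 for neutrophil genes (percentile 0), -0.31 for megakaryocyte genes (percentile 0), -0.29 for inflammatory genes (percentile 0.45) and -0.17 for Toll-like receptor genes (percentile 2.57). It was outside the central range for these lists except the Toll-like receptor genes, which lay just inside. It was also outside for B cell genes (-0.23, percentile 0.06), the eosinophil, basophil and mast cell list (0.38, percentile 99.98) and dendritic cell and MHC class II genes (0.12, percentile 97.75). The same held for immediate early genes (-0.21, percentile 0.62), glucocorticoid-responsive genes (0.11, percentile 98.53) and islet hormone genes (percentile 100). The sign for the eosinophil list is opposite to the gap between its medians. Both control pools enter this difference, and between them neutrophil genes differed by 0.27 and the eosinophil list by 0.35 (percentile 100 in both). Inflammatory genes differed there by 0.41 (percentile 100), immediate early genes by 0.14 (99.13), megakaryocyte genes by -0.17 (0) and dendritic cell and MHC class II genes by -0.12 (1.74). B cell genes (-0.04), glucocorticoid-responsive genes (0.09) and Toll-like receptor genes (0.05) lay inside the central range there. The plot of list medians shows both sexes.

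**Figure D3:**
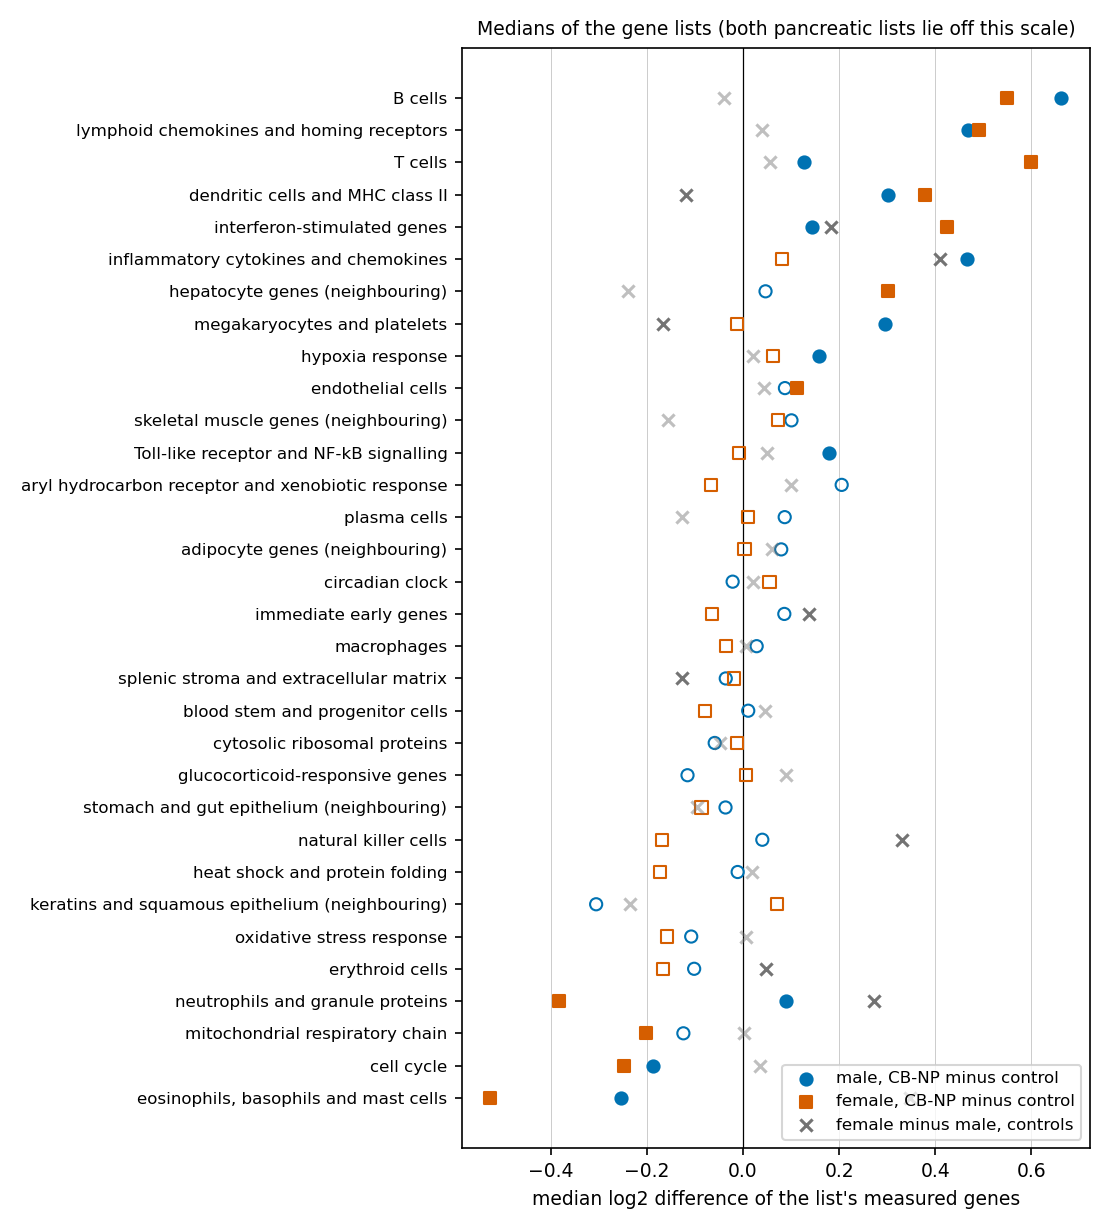
Median log2 difference of CB-NP minus control (horizontal axis) for each gene list (vertical axis) in males and females, 1 pool per group, with filled symbols outside and hollow symbols inside the central range of 10000 random lists, and crosses for the female minus male difference between control pools. B cell genes (0.66 and 0.55) and homing genes (0.47 and 0.49) lie to the right in both sexes, neutrophil genes (0.09 and -0.38) differ, and the pancreatic and X/Y lists are not drawn.

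The remaining lists had small medians, given as males then females, with percentiles. Hypoxia response genes were at 0.16 (99.11) and 0.06 (87.81), mitochondrial respiratory chain genes at -0.12 (6.14) and -0.20 (2.12), endothelial genes at 0.09 (96.87) and 0.11 (97.76) and hepatocyte genes at 0.05 (73.32) and 0.30 (97.69). In each of these 4 lists 1 sex lay outside the central range, and each came inside it under at least 1 alternative (percentiles 94.37, 10.83, 96.45 and 91.71). Inside it in both sexes were macrophages at 0.03 (95.67) and -0.03 (79.62), splenic stroma at -0.04 (56.47) and -0.02 (82.08), erythroid cells at -0.10 (17.67) and -0.17 (6.07), natural killer cells at 0.04 (66.4) and -0.17 (8.50) and plasma cells at 0.09 (83.31) and 0.01 (64.54). So were stem and progenitor cells at 0.01 (84.36) and -0.08 (47.17), aryl hydrocarbon receptor and xenobiotic genes at 0.21 (97.47) and -0.07 (40.73), oxidative stress genes at -0.11 (7.19) and -0.16 (11.36) and heat shock genes at -0.01 (92.98) and -0.17 (8.22). Immediate early genes were at 0.09 (92.52) and -0.07 (30.89), glucocorticoid-responsive genes at -0.12 (4.66) and 0.01 (75.13), circadian clock genes at -0.02 (37.48) and 0.06 (69.58) and ribosomal protein genes at -0.06 (86.31) and -0.01 (96.3). Of the other tissues, adipocyte genes were at 0.08 (73.34) and 0.00 (51.18), skeletal muscle genes at 0.10 (79.85) and 0.07 (62.49), stomach and gut epithelium at -0.04 (41.33) and -0.09 (27.23) and keratins at -0.31 (2.75) and 0.07 (61.74). The X inactivation and Y-linked list was at -0.01 (49.66) in males and had too few measured members in females. Single members of these lists differed more, at measured values that can include readings not well above background. In females these were Slc7a11 (oxidative stress, 2.77, males -0.14), Cry1 (clock, -1.45, males 0.32), Serpina1a (hepatocyte, 1.28, males 0.67) and Tff1 (stomach, -2.54, males -0.13). In males Tff2 of the stomach list was -2.68. With the mean over probes the female aryl hydrocarbon receptor median was 0.42 at percentile 99.87, and the male percentile reached 98.2 under other scalings. With cyclic loess the ribosomal medians were 0.06 and 0.12, and with normexp the female stroma median was 0.09, each then above the central range. Outside the central range were 14 of 35 lists in males, 12 of 34 in females and 11 of 35 for the difference between the sexes, beside 12 of 35 between the control pools.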

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

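The tests of islet genes, of normalization, of the acinar level in the control pools, of the share of the main cell type and of eosinophil carry-over and surface genes were chosen only after the results were seen. For eosinophil carry-over the bound was also changed after its value was seen: a gap over 1 between the control pools first counted against it and now leaves it open. For B cell precursor genes and eosinophil surface genes, the written bound counted a median above 0 in at least 1 sex against the explanation. The male medians (0.14 and 0.16) met that bound. The bound applied also required a median beyond the spread of random lists, which leaves both explanations open. The differences between sexes in this part were not tested, since each rests on 1 pool per group.

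D7Ertd143e was lower in the male CB-NP pool (log2 difference -1.35) and higher in the female CB-NP pool (1.73), which differ by 3.08. Znf41-ps also went opposite ways, at -1.30 and 1.35, which differ by 2.65. Nkpd1 did so at -1.12 and 1.63, which differ by 2.75. All 3 kept these signs under the other normalizations and were nearer to 0 with normexp background correction, as with Nkpd1 at -0.30 and 0.39. The control pools already differed by -1.47, -1.09 and -1.43 (female minus male) for D7Ertd143e, Znf41-ps and Nkpd1, which is about the size of these differences. The neutrophil granule genes had a median of 0.09 in males and -0.38 in females, which differ by -0.47 beside 0.27 between the control pools, and the signs were the same under each alternative run for that list. Among 11530 probes that were not matched to a gene in the name table and were well above background on all 4 arrays, 13 were at least 2-fold different the same way in both sexes. Of these, 3 were higher and 10 lower, against 1.23 and 0.324 for independent lists, and the female minus male differences gave 1 and 0. Examples, chosen after their values were seen, are probes A_55_P2131379 (-2.29 and -2.93) and A_55_P1963724 (-2.12 and -3.15) among the lower, and A_55_P2165154 (1.32 and 1.18) among the higher.

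Pancreatic acinar enzyme genes were lower in both CB-NP pools by list medians of -3.77 and -3.64 with undetected members at their bounds. Normalization is argued against by the median closest to 0 over the normalizations, which was -1.66. More whole pancreas, islets included, in the female control than in the female CB-NP pool is argued against by the female islet median of 0.49. That median rests on 3 measured genes. Islets in both female pools could give the same value, and Ins2 was well above background in both (98.4 and 108 intensity units). Islets in the female control pool are therefore not excluded. The male islet median was -2.37 with undetected members at their bounds. Acinar tissue carried along with both control spleens may account for the pattern, since acinar genes outside the fixed list, picked before their values were seen, lay at or under percentile 0.07 in both sexes, but their medians were only -0.56 and -0.66, with Gp2 (not well above background in either CB-NP pool) at -3.35 and -3.68 and Gatm (0.11 and 0.51) and Nr5a2 (0.21 and 0.41) above 0. That exposure lowered acinar transcripts within the spleen cannot be told apart from this: between the control pools the fixed list differed by -0.05 and the genes outside it by -0.42 (female minus male, percentile 0.97), and neither value decides. In males 5 of 5 measured islet genes were lower as well, which a change in acinar transcripts alone would not cover. Of these, 3 were not well above background in the male CB-NP pool, and the comparison rests on 1 pool per group.

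B cell genes were higher in both CB-NP pools by medians of 0.66 and 0.55. A smaller share of the main cell type would raise all other types alike. It is argued against by a gap of at least 0.57 above the macrophage, natural killer and stroma medians, lists chosen after their medians were seen. T cell medians were 0.13 in males and 0.60 in females, and dendritic cell and MHC class II medians 0.30 and 0.38. A rise shared with these lists is therefore not excluded. Normalization is argued against by a smallest median of 0.44 over the normalizations. A later mix of B cell stages could raise mature genes and lower precursor genes: mature genes outside the lists had medians of 0.70 and 0.51 (13 of 13 above 0 in both sexes), but the median of precursor genes outside the lists, up to 0.14, lay within the spread of random lists and does not decide. Listed precursor genes were not part of that test. Vpreb1, Igll1, Dntt, Rag1 and Rag2 were lower in females (-0.48, -0.82, -0.68, -0.86 and -0.83). In males they went both ways (-0.11, -0.48, 0.20, 0.20 and -0.60). Vpreb3 of the same list was 0.84 in males and 0.35 in females. The explanation stays open. Pups further on in postnatal development remain open too, since growth genes that decline after birth had medians of up to -0.08, inside the central range. An effect of the exposure on B cells stays open and untested beyond these pools.

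Eosinophil granule genes were lower in both CB-NP pools, with medians of -2.47 and -2.23 over 6 genes picked after their values were seen. Normalization is argued against by the median closest to 0, which was -1.67. Eosinophils carried in with pancreatic tissue cannot be told apart from a change in the spleen's own: the female minus male difference of the control pools was larger for granule than acinar genes by 1.15, but resident eosinophils may differ between these pools too. Fewer eosinophils of every stage would lower surface genes too. Their male median was 0.16 (percentile 86.99, 4 genes), so the male values do not show such a fall. In females their median was -0.38 (percentile 1.62, 4 of 5 below 0), below the central range. Between the control pools these genes differed by 0.35 (female minus male, percentile 98.91). The explanation stays open, because 0.16 lies within the spread of random lists and whether other cells supply these transcripts was not tested. An effect of the exposure stays open as a hypothesis.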

How the results depend on the processing

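The comparison without the pancreatic list genes was chosen only after the data were seen, and it kept Cela3a, Sycn and Gm10334, which are not on those lists. No named gene that was at least 2-fold different in the main setting and well above background on at least 1 array of the pair changed sign, whereas named genes nearer to 0 did, and the cause of the moves below was not tested, except that a lower fold threshold or a dropped detection filter admits more genes by construction. With normexp the genes at least 2-fold higher and lower were 13 and 22 in males (main 49 and 72), 23 and 27 in females (93 and 61) and 9 and 4 between control sexes (36 and 74), the correlation was 0.528 (main 0.433), limma called 19 higher and 26 lower (main 1 and 7), and the male T cell median was 0.076, no longer outside the random lists. Without a detection filter the counts were 429 and 662, 647 and 452, and 411 and 614, with 71 higher and 102 lower in both sexes (main 4 and 24), a correlation of 0.19 and 0 limma calls either way (1366 at an unadjusted p under 0.05). At 1.5-fold they were 363 and 284, 616 and 353, and 217 and 358, with 120 and 56 in both sexes. The authors' table gave 140 higher in females, 11 higher in both sexes and 0 and 2 limma calls (2145 unadjusted). Median centring gave 57 and 46 between control sexes and 169 and 171 limma calls, with an unlimited prior. Limma called 0 and 3 with quantile normalization (1974 unadjusted) and with cyclic loess (1966), 0 and 0 on genes detected on all 4 arrays (2114), 2 higher without a sex term, and 226 and 152 with an intensity trend. The correlation was 0.412 with mean probes and 0.399 without pancreatic list genes. Of the counts and correlations, 62 others stayed within their bounds, and of list medians 582 kept their side, 20 came to lie outside the random lists and 11 no longer did. Another 4, near 0 in the main setting, came to lie outside with the opposite sign: ribosomal proteins with cyclic loess (0.062 in males, 0.122 in females), female stroma with normexp (0.093) and female aryl hydrocarbon receptor genes with mean probes (0.419). The B cell medians ranged from 0.49 to 0.72 in males and 0.44 to 0.64 in females, and the acinar medians, with undetected members at their measured values where kept, from -4.45 to -1.66 and -4.54 to -2.07. No paired analysis was possible because the groups share only 1 replicate number, beyond the comparison of treatments within sex in the limma model. Leaving out an array left no residual degree of freedom in the model with sex, and was not run without a sex term; the 4 arrays shared 1 slide. Signal over background limits the dim genes, whose differences with normexp were nearer to 0.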

Other observations

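Mature B cell genes that are on no fixed list were higher in both CB-NP pools. Cd40, a costimulatory receptor, was 0.86 in males and 0.66 in females on the log2 scale, Cd180 was 1.21 and 0.43, Fcmr, the IgM receptor, was 0.75 and 0.72, and Btla was 0.80 and 0.81. In the control pools these genes had a female minus male median of 0.01 (percentile 40.45). Growth genes known to decline after birth, such as Igf2 (-0.19 and 0.13) and Lin28b (-0.40 and -0.09), had medians of -0.09 and -0.08. The lists were written before their values were seen, and the examples were chosen after.

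The pancreatic genes Cela3a, Sycn and Gm10334 are not on the pancreatic lists and are counted here. Of 113 male genes at least 2-fold different outside the pancreatic lists, 16 had another probe well above background on both arrays. That probe differed at least 2-fold the same way for 5 and had the same sign for 12, with a median of 0.615 in the direction of the first probe. Of 148 such female genes, 18 had another probe, with 6 at least 2-fold the same way, 15 of the same sign and a median of 0.803.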
